A study of Mus musculus with 21 samples.

How the data were processed

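RNA was measured in 21 samples on Affymetrix whole-transcript mouse arrays with the WT PLUS assay, which labels total RNA, per the labels. The groups were Py117 culture (3 arrays), Py8119 culture (3), Py117 tumours (5), mixed tumours from a 1:1 implant (5) and Py8119 tumours (5). The deposited values are log2 signals that the authors made by RMA, per the submitters' processing notes, which also name limma. No version was given for either. Background correction and normalization beyond that name were not described. Labels give no hybridization date or batch, so batches could not be examined. Cultures and tumours also differ in sample type, so any batch between them cannot be told apart from it. The number of arrays limits the precision.

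The table held 41345 probe sets. Of these, 23521 were assigned to a single gene symbol, 1814 to several and 16010 to none. Probe sets with a single symbol were used, and for the 1082 genes with several the probe set with the highest mean over the 21 arrays was taken, which gave 22180 genes. Probe sets with several symbols or none were left out because they cannot be assigned to a gene. As a reference for background signal, chosen after the data were seen, 1394 olfactory and vomeronasal receptor genes had a median of 3.27 and a 95th percentile of 5.31.

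Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The culture comparison used the 6 culture arrays and the 3 tumour comparisons used 1 fit of the 15 tumour arrays. Each tumour and culture comparison used the arrays of its line, and the interaction used the arrays of the unmixed groups. Replicate numbers were not used for pairing. Gene lists of cell types, pathways and secreted factors (29 lists, 650 entries, 594 measured) were tested with camera at a preset correlation of 0.01. The p-values were adjusted over the 28 lists with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

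The position of a mixed tumour was the median over genes of its place between the means of Py117 (0%) and Py8119 tumours (100%) on the linear scale. The genes were called in culture with an absolute log2 difference of at least 2 and differed in the same direction by at least 1 in tumours. Genes above or below both parental tumours were those called in the same direction in both mixed comparisons. Sample groups, comparisons, tests, lists, named genes and most alternatives were fixed before the data were examined. The exceptions were the alternatives for fat tissue, the added clock, glucocorticoid and immediate early lists, the positions of gene lists, the tests of Kcnma1 and of immune gene positions, the count of other splits and the background reference.

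Named genes were chosen by rule. For each comparison these were the 10 genes with the largest positive and the 10 with the largest negative difference among called genes whose groups did not overlap. For comparisons of tumour with culture and for the interaction it was 5 and 5, and the interaction had no overlap rule. Predicted, small RNA and receptor genes were left out of this choice. To these were added 15 genes named in advance, the genes of each list with the largest called differences (up to 4), and up to 10 genes on each side outside both parental tumours. Certain genes were not analysed in the text.

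The procedure was tested on simulated data with the same groups. Of 67 genes given a log2 change of 1, 73.1% were recovered in the culture comparison, 95.5% between the parental tumours, 94.0% for mixed against Py117 and 97.0% for mixed against Py8119 tumours. The share was 83.6% for Py117 tumours against culture, 80.6% for Py8119 tumours against culture and 65.7% for the interaction. For a log2 change of 0.5 the shares, in the same order, were 10.4%, 76.1%, 56.7%, 40.3%, 19.4%, 16.4% and 8.96%. A shifted list was found in each comparison, and none of 20 unshifted lists was called in any. The simulated genes were drawn independently of each other, so this does not test list calls among correlated genes. Simulated mixtures with 20, 50 and 80% of Py8119 signal were placed at 21.3%, 49.4% and 80.2%. These mixtures were set as shares of signal, so they check the calculation of the position only. They do not test compression of bright signals on the array or differences in host tissue.

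The alternatives were quantile normalization, centring of each array on its median, leaving out genes in the lower part of the signal range (below the median of gene means), and the mean of all probe sets of a gene. The others were an intensity trend with a robust prior, array weights, 1 fit of all 21 arrays, a replicate block, leaving out each array in turn and a threshold of 0.01. For positions, the log2 scale and other gene choices were tried. After the data were seen, the mean of the adipocyte list was tried as a covariate, and the 3 Py117 tumours with the highest mean were left out.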

Results

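Gene expression was measured on Affymetrix whole-transcript arrays in 21 samples of mouse mammary carcinoma. Py117 and Py8119 are cell lines derived from tumours of MMTV-PyMT mice, which express the polyomavirus middle T oncogene in the mammary gland. The series describes Py117 tumours as sensitive and Py8119 tumours as resistant in their immune response to radiation. It also asks how both lines behave within the same tumour. Cultures were profiled with 3 arrays for each line. Orthotopic tumours were profiled with 5 arrays each for Py117, Py8119 and a 1:1 mixture of both lines. Each tumour started from 1000000 cells implanted in mammary fat pad 4. No sample was irradiated, and tumours were taken on the day radiation would usually have been given.

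The deposited values were log2 signals, and the median of each array lay between 5.24 and 5.53. Arrays within a group correlated across the 22180 genes with r between 0.969 and 0.994, with the widest spread among Py117 tumours (median gene SD 0.205, n = 5). Mixed and Py8119 tumours correlated with r between 0.979 and 0.991, whereas Py117 and Py8119 tumours correlated with r between 0.930 and 0.950. The number of arrays limited the precision of each comparison, and p-values measured differences against the spread between arrays. Log2 differences are given with the standard error from limma, and adjusted p-values come from limma unless stated. Differences against a group mean under 5.31, the 95th percentile of receptor genes used as background, are limited by background.

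The comparison of the cultures asked how the lines differed in the absence of host tissue. Epithelial genes were lower in Py8119 cells, and mesenchymal genes went both ways, with more of them higher. No list in culture passed with an estimated correlation (adjusted p = 0.165 for epithelial and 0.568 for mesenchymal genes). Epcam, an epithelial adhesion molecule, was lower in Py8119 cells (log2 difference -5.51 ± 0.15, adjusted p = 2.06e-06, n = 3 and 3, probe set 17340272), where its mean of 5.07 lay within background. Cdh1, which encodes E-cadherin, differed by -5.09 ± 0.11 and Esrp1, an epithelial splicing regulator, by -5.93 ± 0.09. Sparc, a matrix glycoprotein, was higher in Py8119 cells by 3.75 ± 0.14, as were the mesenchymal transcription factors Snai2 (3.58 ± 0.17) and Zeb1 (2.40 ± 0.20). In all, 5942 of 22180 genes passed adjusted p 0.05, of which 3208 were higher and 2734 lower in Py8119 cells. Of these, 558 and 938 differed at least 2-fold.

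Of 30 epithelial genes, 27 were lower in Py8119 cells (29 adjusted over the list alone) and none was higher. The list passed camera at adjusted p = 3.33e-23, with adjusted p = 0.165 with an estimated correlation. Serpinb5, an epithelial serpin, differed by -6.96 ± 0.21, the membrane protease St14 by -5.63 ± 0.40 and the surface protein Cd24a by -5.71 ± 0.16. Among 19 basal and myoepithelial genes, 5 were lower (5 adjusted over the list alone), including the integrin Itgb4 (-4.81 ± 0.13) and the keratin Krt14 (-4.27 ± 0.18). That list had adjusted p = 0.00623 and adjusted p = 0.426 with an estimated correlation. Among 27 mesenchymal genes, 14 were higher and 8 lower (15 and 9 adjusted over the list alone), with adjusted p = 0.0158 and adjusted p = 0.568 with an estimated correlation. S100a4, a calcium-binding protein of motile cells, differed by 3.54 ± 0.13, the intermediate filament gene Vim by 1.27 ± 0.08 and the receptor tyrosine kinase Axl by 1.34 ± 0.11. Gas6, the ligand of Axl, differed by -0.87 ± 0.27 and did not pass (adjusted p = 0.0532).

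The largest differences outside these lists included the amino acid transporter Slc38a1 (5.19 ± 0.14), the transcription factor Tfap2b (4.25 ± 0.16) and the BMP antagonist Grem1 (4.16 ± 0.20), all higher in Py8119 cells. Timp3, an inhibitor of metalloproteinases, was lower in Py8119 cells (-7.16 ± 0.20), and the iron-binding protein Lcn2 differed by -5.56 ± 0.16. A probe set assigned to Kcnma1, a potassium channel gene, showed the largest difference of all named genes (-7.67 ± 0.15, probe set 17548705). A second Kcnma1 probe set had a mean log2 signal of 4.18, under background, so it cannot check this difference.

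At the preset correlation, the lists of cell cycle and DNA repair genes were higher in cultured Py8119 cells. Of 28 cell cycle genes, 12 were higher and 1 was lower (13 and 1 adjusted over the list alone; adjusted p = 0.000570, and adjusted p = 0.318 with an estimated correlation). They included the replication helicase subunit Mcm2 (1.00 ± 0.10) and the cyclin Ccne1 (0.91 ± 0.11). Of 29 DNA repair genes, 17 were higher and 1 was lower (20 and 1 adjusted over the list alone), with adjusted p = 6.39e-06 and adjusted p = 0.259 with an estimated correlation. Examples were Fancd2 of the Fanconi pathway (0.99 ± 0.09) and the homologous recombination genes Rad51c (0.96 ± 0.09) and Brca2 (0.89 ± 0.10). Of 22 p53 target genes, 13 were lower and 3 higher (15 and 4 adjusted over the list alone), with adjusted p = 0.000176 and adjusted p = 0.165 with an estimated correlation. The cell cycle inhibitor Cdkn1a differed by -1.94 ± 0.12, the apoptosis effector Perp by -3.57 ± 0.09 and Trp53inp1, a p53 cofactor, by -2.81 ± 0.26. The count of higher cell cycle genes was 7 without Py117 culture 3 or Py8119 culture 1, and that of higher DNA repair genes was 11 without Py117 culture 3.

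The cultures also differed in single secreted factors, although the chemokine list had adjusted p = 0.598 and the cytokine list adjusted p = 0.598. Csf3, the granulocyte growth factor G-CSF, was lower in Py8119 cells (-3.48 ± 0.24). The neutrophil chemokine Cxcl5 differed by -3.04 ± 0.22, the chemokine Cxcl16 by -4.44 ± 0.20 and the epithelial cytokine Tslp by -4.49 ± 0.19. The T cell chemokines Cxcl10 (2.08 ± 0.14) and Ccl5 (2.93 ± 0.17) and the monocyte chemokine Ccl2 (1.53 ± 0.28, adjusted p = 0.00605) were higher. Csf1, the macrophage growth factor, differed by 0.34 ± 0.09 (adjusted p = 0.0355), and adjusted p was 0.0678 to 0.122 without Py117 culture 1 or 3 or without any single Py8119 culture. Of 28 interferon response genes, 2 were higher and 2 lower (2 and 2 adjusted over the list alone; adjusted p = 0.872). With genes of the lower part of the signal range left out, the basal list had adjusted p = 0.0628 and the mesenchymal list adjusted p = 0.271.

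The comparison of tumours asked how the same lines differed when growing in the mammary fat pad. Py8119 tumours held less signal from epithelial genes than Py117 tumours. The endothelial, T cell and interferon response lists were also lower at the preset correlation, but not with an estimated one (adjusted p = 0.142, 0.342 and 0.323). Epcam was lower in Py8119 tumours (-5.14 ± 0.21, adjusted p = 3.39e-12, n = 5 and 5), where its mean of 5.13 lay within background. Cxcl9, an interferon-gamma-induced chemokine that attracts T cells, was 19.1-fold lower (-4.25 ± 0.38, adjusted p = 7.19e-08). Csf1 was 3.43-fold higher (1.78 ± 0.12, adjusted p = 1.11e-09). In all, 8299 genes passed, 4648 higher and 3651 lower in Py8119 tumours, and 784 and 1169 of them differed at least 2-fold.

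**Figure D1:**
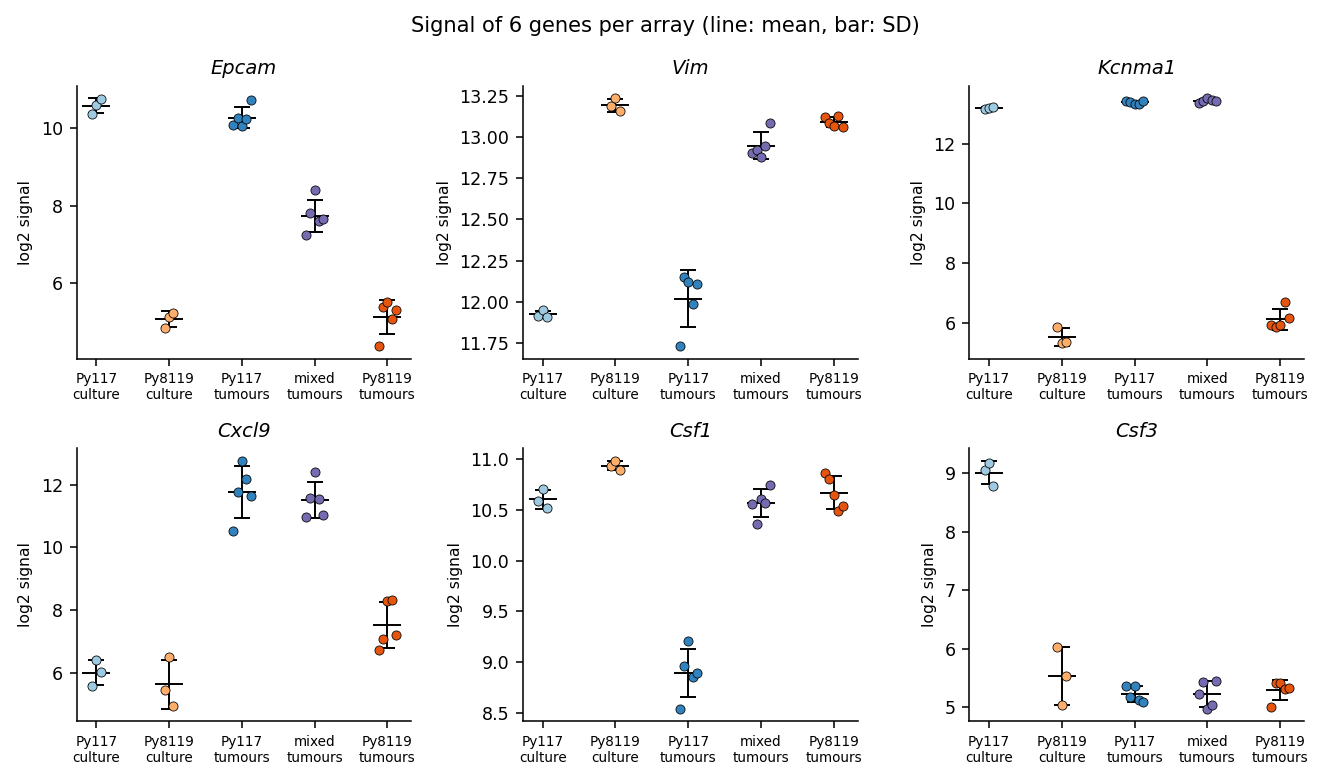
Log2 signal of 6 genes in each of the 21 arrays, by group, with the group mean as a line and the SD as a bar. Epcam lay near 10 in Py117 samples and near 5 in Py8119 samples, and Cxcl9 was lower in the 5 Py8119 tumours than in the other tumours.

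Of 30 epithelial genes, 27 were lower in Py8119 tumours (30 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 1.2e-24 with the preset and 0.0270 with the estimated correlation). Cdh1 differed by -3.64 ± 0.18 and Esrp1 by -5.79 ± 0.13. Of 19 basal and myoepithelial genes, 12 were lower (12 adjusted over the list alone; adjusted p = 6.44e-05, and adjusted p = 0.0812 with an estimated correlation). Of 27 mesenchymal genes, 16 were higher and 6 lower (16 and 7 adjusted over the list alone), with adjusted p = 0.000683 and adjusted p = 0.347 with an estimated correlation. S100a4 differed by 3.76 ± 0.13, Cdh2, which encodes N-cadherin, by 3.65 ± 0.18, Vim by 1.07 ± 0.09 and Axl by 1.57 ± 0.12. Other genes far higher in Py8119 tumours were Ankrd1, a target of mechanical signalling (5.16 ± 0.16), and the surface glycoprotein Msln (4.04 ± 0.09). Igfbp5, which binds insulin-like growth factors, differed by -7.09 ± 0.14, and the Kcnma1 probe set by -7.25 ± 0.12.

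At the preset correlation, lists of vessel and connective tissue genes were lower in Py8119 tumours. All 20 of 20 endothelial genes were lower (20 adjusted over the list alone; adjusted p = 4.38e-14, and adjusted p = 0.142 with an estimated correlation), with a median difference of -1.53. They included the endothelial sialomucin Emcn (-2.15 ± 0.18), Cd34 (-1.97 ± 0.14) and the VEGF receptor Kdr (-1.90 ± 0.16). Of 22 fibroblast genes, 17 were lower and 4 higher (17 and 4 adjusted over the list alone; adjusted p = 7.86e-05, and adjusted p = 0.347 with an estimated correlation). The matrix proteoglycans Lum (-2.63 ± 0.43) and Dcn (-2.02 ± 0.25) were lower, whereas Ogn, a related proteoglycan, was higher (2.10 ± 0.33). Of 10 pericyte genes, 6 were lower and 1 was higher (6 and 1 adjusted over the list alone; adjusted p = 0.0129, and adjusted p = 0.342 with an estimated correlation). Adipocyte genes differed as well. Of 16 adipocyte genes, 12 were lower in Py8119 tumours (13 adjusted over the list alone; adjusted p = 2.26e-05, and adjusted p = 0.347 with an estimated correlation). The lipogenic gene Thrsp differed by -5.12 ± 0.21 and the lipase Lpl by -2.32 ± 0.39. The mean log2 level of the list in the Py117 tumours was 7.72, 5.94, 6.05, 6.97 and 7.76. With that mean as a covariate, 6680 genes passed in place of 8299, and with the 3 Py117 tumours of highest mean left out, 8186 passed. Leaving out these 3 lowers the adipocyte difference by construction (median -0.14, adjusted p = 0.0704, 4 of 16 genes lower).

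**Figure D2:**
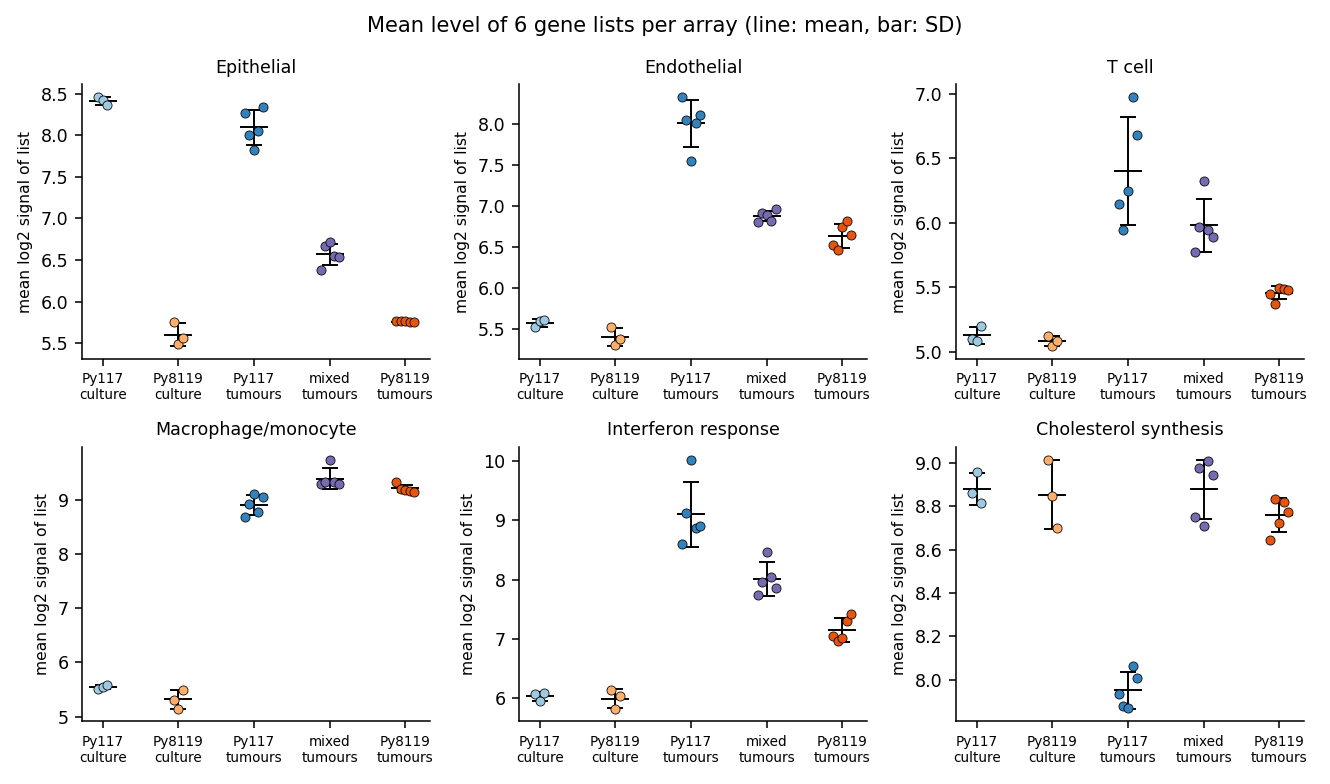
Mean log2 signal of 6 gene lists in each of the 21 arrays, by group, with the group mean as a line and the SD as a bar. Epithelial genes were lowest in Py8119 samples, and the interferon response list was higher in Py117 tumours than in Py8119 tumours.

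At the preset correlation, the lists of T cell, cytotoxic and regulatory T cell genes were lower in Py8119 tumours. Of 20 T cell genes, 18 were lower in Py8119 tumours (19 adjusted over the list alone) and none was higher (adjusted p = 2.19e-07, and adjusted p = 0.342 with an estimated correlation). The T cell receptor subunit Cd3g differed by -2.24 ± 0.32, and Cd8a, a coreceptor of cytotoxic T cells, by -1.56 ± 0.28 (adjusted p = 0.000157). With the adipocyte mean as a covariate 9 T cell genes were lower (list adjusted p = 0.000903), and without the 3 Py117 tumours of highest mean 13 were. Of 20 cytotoxic and natural killer genes, 8 were lower and 1 was higher (9 and 1 adjusted over the list alone; adjusted p = 0.00952, and adjusted p = 0.490 with an estimated correlation). The higher gene was the interleukin-18 receptor subunit Il18rap (2.34 ± 0.19). Of 19 regulatory T cell and checkpoint genes, 12 were lower and 2 higher (12 and 2 adjusted over the list alone; adjusted p = 0.000872, and adjusted p = 0.349 with an estimated correlation). Foxp3, the transcription factor of regulatory T cells, differed by -1.03 ± 0.18 (adjusted p = 0.000125). Cd274, which encodes PD-L1, differed by -0.90 ± 0.34 (adjusted p = 0.0435), and adjusted p was 0.0632 to 0.125 without Py117 tumour 3, 4 or 5 or without any single Py8119 tumour.

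Of 28 interferon response genes, 26 were lower in Py8119 tumours (26 adjusted over the list alone), with a median difference of -1.95 (adjusted p = 3.49e-16, and adjusted p = 0.323 with an estimated correlation). Irf7, a transcription factor of the interferon response, differed by -3.43 ± 0.25, the antiviral gene Ifit1 by -3.24 ± 0.28 and the interferon feedback regulator Usp18 by -3.10 ± 0.32. Cxcl10, another interferon-induced chemokine, differed by -1.97 ± 0.41 (adjusted p = 0.000709), opposite in sign to its difference in culture. Of 18 genes of MHC class I presentation, 12 were lower (12 adjusted over the list alone; adjusted p = 7.28e-06, and adjusted p = 0.347 with an estimated correlation). They included the peptide transporter Tap1 (-2.63 ± 0.25) and the nonclassical molecule H2-T23 (-2.84 ± 0.28). Of 13 MHC class II genes, 7 were lower and 2 higher (8 and 2 adjusted over the list alone; adjusted p = 0.0124, and adjusted p = 0.395 with an estimated correlation). The count of higher MHC class II genes was 1 without Py117 tumour 1, 2 or 4 or Py8119 tumour 1, 2 or 5.

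Macrophage genes went mostly the other way. Of 29 macrophage and monocyte genes, 16 were higher in Py8119 tumours and 6 lower (18 and 7 adjusted over the list alone; adjusted p = 0.0231, and adjusted p = 0.406 with an estimated correlation). The arginine-degrading enzyme Arg1 differed by 2.98 ± 0.51 and the scavenger receptor Msr1 by 2.06 ± 0.15, whereas the monocyte marker Ly6c2 was lower (-2.70 ± 0.42). The Csf1 receptor gene Csf1r was higher by 0.40 ± 0.12 (adjusted p = 0.0106), and Il34, its second ligand, by 2.17 ± 0.09. Chemokine genes moved both ways, with 10 of 33 higher and 11 lower (10 and 11 adjusted over the list alone). The list did not pass (adjusted p = 0.780), and its median (-0.28), mean (-0.10) and camera direction were negative while fry pointed upward. Ccl2 was higher by 2.15 ± 0.36, and the monocyte chemokine Ccl8 was lower (-2.25 ± 0.48). Of 21 dendritic cell genes, 9 were lower and 4 higher (10 and 4 adjusted over the list alone; adjusted p = 0.0204, and adjusted p = 0.349 with an estimated correlation). Csf3, which differed in culture, differed by 0.07 ± 0.11 in tumours (adjusted p = 0.702).

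Lists of cell cycle, repair and sterol genes were higher in Py8119 tumours at the preset correlation. Of 28 cell cycle genes, 20 were higher and none was lower (22 and 0 adjusted over the list alone; adjusted p = 4.82e-06, and adjusted p = 0.347 with an estimated correlation). The mitotic transcription factor Foxm1 differed by 1.12 ± 0.11 and the kinesin Kif20a by 1.12 ± 0.13. Of 29 DNA repair genes, 18 were higher and 1 was lower (23 and 1 adjusted over the list alone; adjusted p = 1.18e-05, and adjusted p = 0.347 with an estimated correlation), among them Brca2 (0.95 ± 0.18) and Fancd2 (0.96 ± 0.14). Of 19 cholesterol synthesis genes, 16 were higher and none was lower (17 and 0 adjusted over the list alone; adjusted p = 7.09e-09, and adjusted p = 0.142 with an estimated correlation). Msmo1, a sterol oxidase, differed by 2.11 ± 0.09 and Fdps, which makes farnesyl diphosphate, by 1.52 ± 0.10. Of 22 p53 target genes, 14 were lower and 4 higher (14 and 4 adjusted over the list alone; adjusted p = 0.00133, and adjusted p = 0.324 with an estimated correlation), with Perp at -3.74 ± 0.15.

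The remaining lists showed smaller or no shifts between the tumours. Of 13 milk and secretory genes, 4 were lower (4 adjusted over the list alone; adjusted p = 0.0124, and adjusted p = 0.324 with an estimated correlation). Adjusted p was 0.388 for neutrophil genes, 0.200 for B and plasma cell genes, 0.0736 for mast cell and eosinophil genes and 0.872 for cytokine genes. It was 0.203 for hypoxia and glycolysis genes, 0.483 for skeletal muscle genes and 0.175 for nerve and Schwann cell genes. For the cytokine list the median (-0.08) and mean (-0.05) were negative while fry pointed upward. Too few red blood cell genes were measured for a test (2). The dendritic list lost its call without Py117 tumour 5 (adjusted p = 0.0804), and the lists of dendritic cells, macrophages and regulatory T cells lost theirs with the genes of lower signal left out (adjusted p = 0.238, 0.151 and 0.168). With the adipocyte mean as a covariate, adjusted p was 0.562 for dendritic, 0.149 for macrophage, 0.132 for MHC class II, 0.120 for regulatory T cell and 0.0920 for pericyte genes. Lower genes then numbered 4 for dendritic, 4 for MHC class II and 5 for regulatory T cell genes, and 10 macrophage and 2 fibroblast genes were higher. Without the 3 Py117 tumours of highest adipocyte mean, adjusted p was 0.373 for dendritic, 0.0537 for macrophage, 0.0870 for MHC class II and 0.0723 for regulatory T cell genes. The adipocyte mean itself differed between the parental tumours, and leaving out arrays lowers precision. Lost calls and lower counts with these 2 alternatives therefore do not by themselves show smaller differences. The macrophage list had adjusted p = 0.0681 with all 21 arrays in 1 fit.

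The line differences of culture and tumours were compared to see which occurred in both settings. Of the 5942 genes that differed in culture, 3957 (66.6%) passed in tumours in the same direction and 262 in the opposite one, against 1122 in the same direction from independent lists. Of the 1496 that differed at least 2-fold in culture, 1221 (81.6%) passed in the same direction and 50 in the opposite one. Across the 22180 genes, the differences correlated with Pearson r = 0.629 (jackknife SE 0.0222 over arrays) and Spearman rho = 0.529. Genes are not independent replicates, so no p-value is given. Epcam, Cdh1, Vim, Axl and S100a4 kept their direction.

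**Figure D3:**
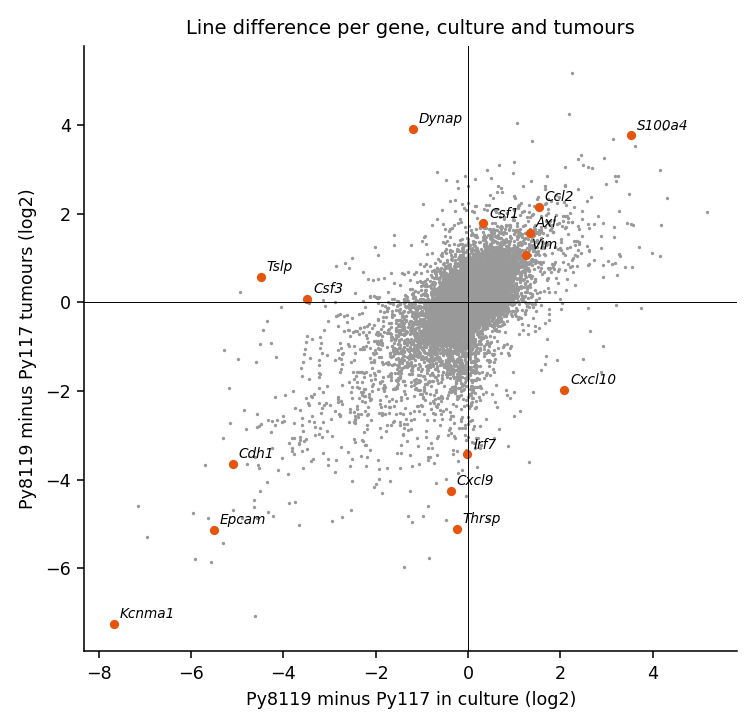
Line difference (Py8119 minus Py117, log2) of each of 22180 genes in tumours against the same difference in culture. The differences rose together, with a Pearson r of 0.629 across genes.

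The interaction asked which line differences changed between culture and tumour, and 2992 genes passed, 1664 with a more positive and 1328 with a more negative difference in tumours. Gbp4 and Cxcl9 separated the lines in tumours more than in culture and Cxcl10 changed direction, whereas Tslp, Csf3, Bpifb4 and Car9 separated them more in culture. Gbp4, an interferon-induced GTPase, had an interaction of -4.93 ± 0.78 (adjusted p = 0.000307), Cxcl10 of -4.05 ± 0.59 and Cxcl9 of -3.89 ± 0.65. Tslp had 5.06 ± 0.29 and Csf3 3.55 ± 0.24, both of which fell in Py117 tumours relative to Py117 cells (-4.82 and -3.78). Bpifb4, a lipid-binding protein of secretory epithelia, had 5.17 ± 0.26, and Car9, a hypoxia-induced carbonic anhydrase, 4.22 ± 0.57.

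Of 28 interferon response genes, 23 had a more negative line difference in tumours (25 adjusted over the list alone; adjusted p = 3.15e-21, and adjusted p = 0.222 with an estimated correlation). The same held for 15 of 20 endothelial genes (16 adjusted over the list alone; adjusted p = 1.64e-13, and adjusted p = 0.161 with an estimated correlation) and 12 of 18 MHC class I genes (13 adjusted over the list alone; adjusted p = 3.59e-09, and adjusted p = 0.265 with an estimated correlation). It held for 7 of 20 T cell genes (15 adjusted over the list alone; adjusted p = 2.6e-08, and adjusted p = 0.265 with an estimated correlation), and that count was 4 without Py117 culture 1 or 2 or Py8119 culture 2 and 12 without Py117 tumour 2. Cholesterol synthesis genes moved the other way, with 12 of 19 more positive (16 adjusted over the list alone; adjusted p = 2.2e-12, and adjusted p = 0.152 with an estimated correlation).

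The comparison of each tumour with its own culture asked what the host tissue and growth in the animal added. Macrophage genes were higher in tumours of both lines, at the preset and at an estimated correlation. The fibroblast, endothelial and interferon response lists were higher and the cell cycle list lower at the preset correlation but not with an estimated one (adjusted p = 0.0865, 0.0865, 0.162 and 0.201 in Py117 and 0.0994, 0.0685, 0.0994 and 0.0685 in Py8119). In Py117, Ctss, a lysosomal protease of antigen-presenting cells, was higher in tumours (7.51 ± 0.19, adjusted p = 4.1e-09, n = 5 and 3). In Py8119, the myeloid receptor Lilrb4a was higher (8.10 ± 0.20, adjusted p = 2.69e-09, n = 5 and 3), and both genes lay within background in culture (means 4.81 and 4.05). In Py117, 6811 genes passed, 2759 higher and 4052 lower in tumours, with 1331 and 788 of them changed at least 2-fold. In Py8119, 8234 passed, 3606 higher and 4628 lower, with 1082 and 475 of them changed at least 2-fold. The split depended on the scaling: with each array centred on its median, the higher share went from 40.5% to 26.3% in Py117 and from 43.8% to 23.4% in Py8119. That centring moved the median of all genes from -0.09 to -0.22 in Py117 and from -0.05 to -0.22 in Py8119.

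Of 29 macrophage genes, 26 were higher in Py117 tumours (27 adjusted over the list alone; adjusted p = 1.34e-28) and 28 in Py8119 tumours (28 adjusted over the list alone; adjusted p = 1.23e-27). Both calls held with an estimated correlation (adjusted p = 0.00820 and 0.0251). The complement gene C1qb and the lysozyme gene Lyz2 were among the largest in Py8119 (6.78 ± 0.32 and 7.28 ± 0.35), and Csf1r was higher by 4.38 ± 0.14 in Py117 and 4.34 ± 0.14 in Py8119. Of 22 fibroblast genes, 21 were higher in Py117 (21 adjusted over the list alone; adjusted p = 1.74e-23, and adjusted p = 0.0865 with an estimated correlation) and 17 in Py8119 (18 adjusted over the list alone; adjusted p = 2e-11, and adjusted p = 0.0994 with an estimated correlation). The median rise of fibroblast genes was 3.29 in Py117 and 1.84 in Py8119, and that of endothelial genes 2.36 and 1.03. Endothelial genes were higher in 17 of 20 cases in Py117 (18 adjusted over the list alone; adjusted p = 4.99e-20, and adjusted p = 0.0865 with an estimated correlation) and in 16 in Py8119 (17 adjusted over the list alone; adjusted p = 3.67e-10, and adjusted p = 0.0685 with an estimated correlation).

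Interferon response genes were higher in 26 of 28 cases in Py117 tumours, with a median rise of 3.21 (26 adjusted over the list alone; adjusted p = 7e-24, and adjusted p = 0.162 with an estimated correlation). In Py8119 tumours 24 were higher, with a median rise of 1.07 (25 adjusted over the list alone; adjusted p = 3.16e-12, and adjusted p = 0.0994 with an estimated correlation). Cxcl9 rose by 5.78 ± 0.40 in Py117 and 1.89 ± 0.43 in Py8119. Cxcl10 rose by 3.55 ± 0.52 in Py117 and fell by 0.50 in Py8119 (adjusted p = 0.0123, and 0.0503 without Py8119 culture 2). Gas6 rose in both (2.69 ± 0.21 and 2.98 ± 0.16), and Csf1 fell by 1.71 in Py117. MHC class II genes were higher in 10 of 13 cases in Py117 (11 adjusted over the list alone; adjusted p = 1.43e-12, and adjusted p = 0.0865 with an estimated correlation) and in 10 in Py8119 (10 adjusted over the list alone; adjusted p = 2.22e-09), where the call held with an estimated correlation (adjusted p = 0.0303).

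Cell cycle genes were lower in 27 of 28 cases in Py117 tumours (27 adjusted over the list alone; adjusted p = 5.16e-14, and adjusted p = 0.201 with an estimated correlation) and in 27 in Py8119 tumours (27 adjusted over the list alone; adjusted p = 6.42e-14, and adjusted p = 0.0685 with an estimated correlation). The mitotic kinase Plk1 fell by 1.52 in Py117, beyond the shift of all genes. Cholesterol synthesis genes were lower in 18 of 19 cases in Py117 (18 adjusted over the list alone; adjusted p = 4.85e-10, and adjusted p = 0.0865 with an estimated correlation), whereas in Py8119 4 were lower and 2 higher (4 and 2 adjusted over the list alone; adjusted p = 0.512). Culture and tumour samples differed in cell composition and growth conditions at once, so these differences cannot be assigned to either.

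The mixed tumours asked how the lines behaved in the same tumour after a 1:1 implant. Their profile lay close to that of Py8119 tumours. On the linear scale, 330 genes that separated the lines in culture and in tumours placed the mixed tumours 87.5% ± 3.08 (SD, n = 5) of the way from Py117 to Py8119 tumours, with a range of 84.4% to 92.3%. All 5 lay above the midpoint of 50% (exact sign-flip permutation test, two-sided, p = 0.063, the smallest 5 tumours allow). The 243 genes higher in Py117 gave 86.9% ± 3.34 (SD, n = 5) and the 87 higher in Py8119 gave 93.6% ± 4.38 (SD, n = 5). Placed the same way, single Py117 tumours lay at 1.05% ± 6.75 and single Py8119 tumours at 99.95% ± 0.376 (SD, n = 5 each). Epcam lay at 84.8% ± 5.70, Cdh1 at 85.7% ± 5.75 and Esrp1 at 86.7% ± 3.03 (SD, n = 5). This position is a share of array signal, and it measures a share of cells only if both lines give equal RNA and linear signals. A share of cells also needs equal host tissue in all groups and unchanged expression of each line beside the other. The endothelial, fibroblast and adipocyte lists differed between the parental tumours at the preset correlation.

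The positions of gene lists, a measure chosen after the data were seen, were not alike. Endothelial genes (14 usable) lay at 90.1% ± 3.43, adipocyte genes (10) at 99.5% ± 2.59 and fibroblast genes (13) at 92.7% ± 14.4 (SD, n = 5). Interferon response genes (24) lay at 77.3% ± 11.6, MHC class I genes (8) at 53.6% ± 25.1, T cell genes (8) at 55.3% ± 22.5 and chemokine genes (5) at 24.7% ± 45.7 (SD, n = 5). Mixed tumour 3 had the lowest position for each of the last 4 lists, with 11.1% for MHC class I and 58.6% for interferon response genes. For chemokine genes it lay at -49.8%, and their mean was 43.4% without it and 13.9% without mixed tumour 5.

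**Figure D4:**
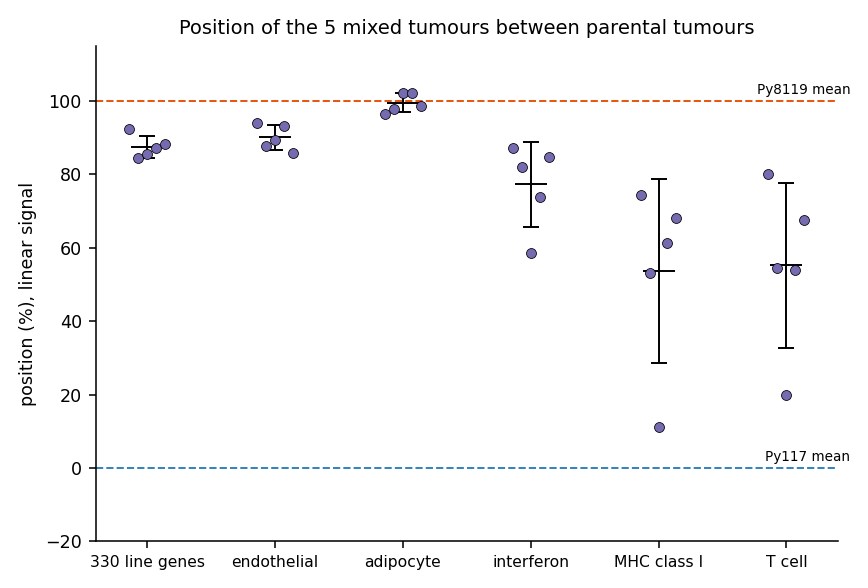
Position of each of the 5 mixed tumours between the mean of Py117 tumours (0%) and that of Py8119 tumours (100%), on linear signal, for the 330 line genes and 5 gene lists, with mean and SD. The line genes lay between 84.4% and 92.3%, and MHC class I and T cell genes spread from 11.1% upward.

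Against Py117 tumours, mixed tumours differed in many genes, among them genes that separated the lines. Ankrd1 was 39.0-fold higher (5.29 ± 0.16, adjusted p = 2.01e-13, n = 5 and 5), S100a4 differed by 3.72 ± 0.13, Cdh2 by 3.59 ± 0.18 and Axl by 1.54 ± 0.12. Epcam differed by -2.53 ± 0.21 and Cdh1 by -2.26 ± 0.18. In all, 8007 genes passed, 4263 higher and 3744 lower in mixed tumours, and 630 and 824 of them differed at least 2-fold. Csf1 (1.68 ± 0.12), Ccl2 (2.57 ± 0.36) and Arg1 (3.03 ± 0.51) were higher. Cxcl9 differed by -0.27 ± 0.38 (adjusted p = 0.631) and Cxcl10 by 0.21 ± 0.41 (adjusted p = 0.732), so neither passed. Cd8a differed by -0.55 ± 0.28 (adjusted p = 0.133), and it passed without Py117 tumour 2 (-0.84, adjusted p = 0.00548).

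Of 30 epithelial genes, 29 were lower in mixed than in Py117 tumours (29 adjusted over the list alone; adjusted p = 7.53e-20, and adjusted p = 0.0587 with an estimated correlation). Endothelial genes were lower in 19 of 20 cases (19 adjusted over the list alone; adjusted p = 4.62e-12, and adjusted p = 0.165 with an estimated correlation). Interferon response genes were lower in 23 of 28 cases (26 adjusted over the list alone; adjusted p = 1.61e-08, and adjusted p = 0.367 with an estimated correlation), with Irf7 at -2.05 ± 0.25. Macrophage genes were higher in 17 and lower in 3 of 29 cases (18 and 3 adjusted over the list alone; adjusted p = 0.000469, and adjusted p = 0.367 with an estimated correlation), and cholesterol synthesis genes were higher in 16 of 19 (17 adjusted over the list alone; adjusted p = 4.62e-12, and adjusted p = 0.0744 with an estimated correlation). T cell genes were lower in 7 of 20 cases (8 adjusted over the list alone; adjusted p = 0.00654, and adjusted p = 0.584 with an estimated correlation), a call lost with the adipocyte mean as a covariate (2 lower, adjusted p = 0.423) and without the 3 Py117 tumours of highest mean (2 lower, 0.499). With the covariate, 10 macrophage genes were higher. Adipocyte genes were lower in 13 of 16 cases (16 adjusted over the list alone; adjusted p = 1.79e-05, and adjusted p = 0.367 with an estimated correlation). Leaving out the 3 Py117 tumours of highest adipocyte mean lowers this difference by construction (4 of 16 lower, adjusted p = 0.0877). MHC class I genes did not pass as a list (adjusted p = 0.118).

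Against Py8119 tumours, mixed tumours differed in far fewer genes, and most of them were higher. In all, 394 genes passed, 358 higher and 36 lower, and 171 and 1 of them differed at least 2-fold. The count of lower genes was 20, 11 and 14 without mixed tumour 1, 2 and 3 and 17, 15 and 21 without Py8119 tumour 1, 2 and 3. It was 231 of 907 with array weights, 55 after quantile normalization, 60 without genes of lower signal and 63 with all 21 arrays in 1 fit. The named genes included epithelial genes of Py117 cells and interferon-induced genes, and the naming rule also drew genes from the lists of both. Epcam was higher (2.61 ± 0.21, adjusted p = 7.25e-07, n = 5 and 5) and Cxcl9 15.9-fold higher (3.99 ± 0.38, adjusted p = 5.44e-06). Lcn2 differed by 4.28 ± 0.13, Igfbp5 by 5.18 ± 0.14, Esrp1 by 3.02 ± 0.13 and Cdh1 by 1.38 ± 0.18. The interferon-induced GTPases Iigp1 (3.57 ± 0.31) and Gbp4 (3.30 ± 0.52), Cxcl10 (2.18 ± 0.41) and Ccl8 (2.68 ± 0.48) were also higher. The Kcnma1 probe set stood apart: it differed by 7.31 ± 0.12 and its level was near that of Py117 tumours (13.44 against 13.38 on the log2 scale). Axl (-0.03 ± 0.12), Csf1 (-0.10 ± 0.12) and Ccl2 (0.42 ± 0.36) did not pass (adjusted p = 0.946, 0.756 and 0.654). Cd8a differed by 1.01 ± 0.28 (adjusted p = 0.0802) and Cd274 by 1.21 ± 0.34 (adjusted p = 0.0894), and neither passed. Standard errors here were pooled over the 3 tumour groups. Cd8a spread most in Py117 tumours (SD 0.81, against 0.31 in mixed and 0.17 in Py8119 tumours). Those tumours, which are not part of this comparison, therefore enlarged its standard error.

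Of 30 epithelial genes, 15 were higher in mixed than in Py8119 tumours (16 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 4.09e-31 with the preset and 0.0106 with the estimated correlation). Of 28 interferon response genes, 13 were higher (23 adjusted over the list alone; adjusted p = 9.17e-28, and adjusted p = 0.173 with an estimated correlation), including Gbp3 (1.70 ± 0.32) and the nucleic acid sensor Zbp1 (1.62 ± 0.32). Of 18 MHC class I genes, 8 were higher (11 adjusted over the list alone; adjusted p = 4.71e-15, and adjusted p = 0.173 with an estimated correlation), including Tap1 (1.61 ± 0.25). Of 13 MHC class II genes, 4 were higher (7 adjusted over the list alone; adjusted p = 8.93e-07, and adjusted p = 0.173 with an estimated correlation), including H2-Aa (1.14 ± 0.17). Among T cell genes 1 of 20 was higher, namely Cd3g at 1.66 ± 0.32 (11 adjusted over the list alone; adjusted p = 5.16e-12, and adjusted p = 0.173 with an estimated correlation). Among cytotoxic and natural killer genes 4 of 20 were higher (12 adjusted over the list alone; adjusted p = 3.91e-11, and adjusted p = 0.173 with an estimated correlation), including the activating receptor Klrk1 (1.35 ± 0.26). Macrophage genes had adjusted p = 0.0220 (0.471 as adjusted p with an estimated correlation), which was 0.297 without mixed tumour 3, 0.186 without Py8119 tumour 4, 0.0784 without Py8119 tumour 5, 0.283 without genes of lower signal and 0.0740 with array weights. At the preset correlation 17 of 28 lists were called, all higher, against 1 with an estimated correlation. Besides those above, they were the endothelial, regulatory T cell, chemokine, dendritic, neutrophil, p53 target, cholesterol synthesis, cytokine, hypoxia and mast cell lists. No endothelial, cholesterol synthesis, hypoxia or mast cell gene passed. Without some single array, the cytokine, hypoxia and mast cell calls were lost (highest camera adjusted p = 0.0523, 0.227 and 0.0642). Cell cycle, mesenchymal and fibroblast lists did not pass (adjusted p = 0.246, 0.650 and 0.246). Some of these counts of higher genes rested on single tumours. For interferon response genes the count was 8 without mixed tumour 3 and 7 without Py8119 tumour 1. For MHC class I genes it was 3 without mixed tumour 2 or 3 or Py8119 tumour 1, 2 or 3, 4 without Py8119 tumour 5 and 5 without mixed tumour 4 or 5. For cytotoxic genes it was 1 without mixed tumour 3 or Py8119 tumour 1 and 2 without mixed tumour 4 or Py8119 tumour 2, 3 or 5.

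A gene above or below both parental tumours cannot follow from averaging the lines, and 23 genes were called so, 8 above and 15 below. Of the 15, 8 had all 3 group means under the background reference of 5.31, among them Fat3, Matn1, Dll3, Nron and Slc6a13, so their differences cannot be read as changes in expression. Among those above were the lymphocyte chemokine Xcl1 (0.78 against Py117 and 1.12 against Py8119 tumours), the lymphocyte surface protein Cd48 (0.43 and 0.67), the transporter Abcg3 (0.43 and 0.81) and the secretory pathway gene Creld2 (0.32 and 0.45). Pik3cd, Sdf2l1 and Tec were also above. Among those below were the clock gene Per1 (-1.80 and -1.20), Depp1, a target of FOXO factors (-1.39 and -0.63), and Tsc22d3, a glucocorticoid-induced gene (-0.82 and -0.53), with Fat3, Matn1, Dll3, Taf8, Ajm1, Nron and Slc6a13. In 100 simulations with no effect, no gene fell above or below both. These simulations drew the 3 groups alike, unlike the data, where 8007 genes passed against Py117 tumours. They therefore give no expected number for the genes called here. Independent lists of the observed sizes gave 68.8 above and 6.08 below. With the mixed arrays divided so that each parental comparison used different ones, a median of 2 above and 2 below were called over 10 divisions. Each comparison then had fewer mixed arrays and less power, so the lower count cannot be assigned to the shared arrays. Whether the genes called in these divisions were among the 23 was not examined. The count was 44 without Py117 tumour 3, 10 and 12 without mixed tumour 2 and 3, and 14, 13, 14 and 14 without Py8119 tumour 1, 2, 4 and 5. With array weights it was 87, and after quantile normalization 15. Per1, Cd48, Abcg3 and Creld2 kept both calls when any single tumour was left out. The other named genes lost at least 1, with Xcl1 at adjusted p = 0.0538 without mixed tumour 3 and 0.0541 without Py8119 tumour 1.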

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

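The splits of the arrays were counted after the results were seen, whereas the test of single arrays far from their group and the interaction test were chosen before the data were examined.

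The difference between the lines was not the same in tumours and in culture for 2992 genes. Of 100 splits only the real one reached this count, and the highest other gave 1335. These splits reassigned the lines within tumours and within cultures, which removes the line differences themselves along with any interaction. They therefore cannot decide whether chance gave the count of the interaction. Genes with a more positive line difference in tumours included Bpifb4 (5.17), Dynap (5.11), Tslp (5.06), Car9 (4.22), Bpifb3 (3.96) and Csf3 (3.55). Cdh1 (1.46) and Csf1 (1.44) were also more positive. The neutrophil gene S100a8 (0.96) passed as well, but its means in cultures and tumours of both lines (3.83 to 4.73) lay under the background reference. Its value therefore cannot be read as a change in expression. Genes with a more negative line difference in tumours included the alternative macrophage activation gene Retnla (-5.32), Gbp4 (-4.93), Scrg1 (-4.92), Thrsp (-4.88), Capn6 (-4.60), Cxcl10 (-4.05) and Cxcl9 (-3.89). Cd274 (-1.40, adjusted p = 0.0362) and Cd8a (-1.49, adjusted p = 0.0274) passed narrowly. Without any single culture array the adjusted p of Cd8a was 0.0504 to 0.0602. That of Cd274 was 0.0521 to 0.109 without Py117 culture 1, 2 or 3, Py8119 culture 1 or 3, Py117 tumour 4 or Py8119 tumour 2, 3, 4 or 5.

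By gene list, the median interaction was -1.81 for interferon response, -1.56 for fibroblast, -1.29 for endothelial, -1.20 for MHC class I, -0.98 for adipocyte, -0.71 for T cell, -0.62 for regulatory T cell and -0.55 for MHC class II genes. It was -0.29 for cytotoxic, -0.20 for hypoxia and -0.16 for milk genes. It was 0.76 for cholesterol synthesis, 0.49 for macrophage, 0.31 for p53 target and 0.31 for epithelial genes. None of these 15 list calls held with an estimated correlation, for which adjusted p was 0.265 for fibroblast, 0.424 for adipocyte, 0.296 for macrophage and 0.424 for epithelial genes. It was 0.630 for cytotoxic, 0.424 for regulatory T cell, 0.265 for MHC class II, 0.630 for hypoxia, 0.424 for p53 target and 0.265 for milk genes. Without Py117 tumour 3, adjusted p was 0.134 for cytotoxic, 0.152 for hypoxia, 0.0657 for p53 target and 0.0987 for milk genes. The cytotoxic call was also lost without Py8119 culture 2 (0.0536) or Py8119 tumour 1 (0.0513). The p53 call was lost without Py117 culture 1 (0.0628), Py8119 culture 1 (0.0543) or Py8119 tumour 3 or 4 (0.0519 and 0.0530). Without genes of lower signal, adjusted p was 0.107 for p53 target and 0.0905 for regulatory T cell genes. With array weights it was 0.0986 for cytotoxic, just over 0.05 for p53 target and 0.0834 for milk genes, after quantile normalization 0.0850 for p53 target and 0.0772 for milk genes, and in 1 fit of all 21 arrays 0.0516 for milk genes. The milk call was lost without Py117 culture 2 (0.0626), Py8119 culture 2 (0.0754) or Py8119 tumour 1 or 3 (0.0513 and 0.0521).

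Of 496 tests of a single array against its group of 5, 29 passed Dixon's 95% critical value of 0.71, and chance alone passes about 1 in 20. They comprised 7 of 165 tests in Py117 tumours, 15 of 166 in mixed tumours and 7 of 165 in Py8119 tumours. Among Py117 tumours, tumour 3 had high H2-T23 (10.70) and Tslp (6.05) and low Brca2 (5.75). Py117 tumour 4 had low S100a4 (7.27), tumour 5 high Cxcl5 (6.44) and tumour 1 low Brinp3 (4.75) and Slc6a13 (5.11).

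Mixed tumour 3 had high Ccl5 (11.14), Ccl2 (10.68), Ifit1 (8.92) and Usp18 (9.16) and low Nr1d1 (7.96) and Lilrb4a (11.92). Its list means were high for cytotoxic (7.59) and macrophage genes (9.75) and low for cell cycle genes (8.99). Mixed tumour 1 had low Esrp1 (7.32) and high Fabp4 (9.09), tumour 4 high Foxp3 (6.05) and low Dll3 (4.02), and tumour 5 high Tigit (6.60) and pericyte genes (6.76). Among Py8119 tumours, tumour 4 had high Slc38a1 (10.24), Sparc (11.98) and Pck1 (5.82) and low Scrg1 (4.10), and tumour 1 had low Ccl5 (8.84), Csf3 (5.00) and Capn6 (5.54). Values are log2 signals or, for lists, mean log2 signals. No technical explanation was tested for these arrays.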

How the results depend on the processing

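The alternatives for fat tissue were chosen after the results were seen, and the others before the data were examined. Of 15479 values of 843 named gene results, 14683 kept their direction and their side of the threshold, 734 no longer passed, 54 newly passed and 8 reversed. Of 2052 values of 110 called list results, 1986 were kept, 64 no longer passed and 2 reversed. At adjusted p 0.01 the counts were 3653 in culture, 224 for mixed against Py8119 tumours, 4495 for Py117 tumours against culture and 1674 for the interaction, where the stricter threshold is the cause. With an estimated correlation the lists called were 0 in culture, 1 between parental tumours, 0 and 1 for mixed against Py117 and Py8119 tumours, 1 and 4 for Py117 and Py8119 tumours against culture, and 0 for the interaction. With fry, 14 lists passed in culture and 4 for mixed against Py8119 tumours. Array weights gave 907 genes for mixed against Py8119 tumours and 87 outside both parents, and quantile normalization gave 15 outside both. The position was 75.4% on the log2 scale, and the correlation was 0.671 without the lower part of the genes. Where no cause is named, the cause was not tested.

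With the adipocyte mean as a covariate, the adipocyte list reversed to 0.26 between parental tumours and 0.088 for mixed against Py117 tumours, which follows from the covariate. So did Fabp4 (1.19 and 1.17) and Pck1 (0.71 and 0.58), and Mcpt4 reversed between parental tumours (0.26). Without the 3 Py117 tumours of highest adipocyte mean, Mcpt4 was at 0.010 and Fabp4 at 0.092 between parental tumours, and Fabp4 was at 0.28 for mixed against Py117 tumours, which for Fabp4, a gene of that list, follows from the choice of tumours, and for Mcpt4 the cause was not tested.

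Leaving out single arrays gave 4319 to 5403 genes in culture, 7667 to 8349 between parental tumours, 7160 to 8136 and 270 to 393 for mixed against Py117 and Py8119 tumours, 5200 to 7800 and 6892 to 7834 for Py117 and Py8119 tumours against culture, and 2328 to 3648 for the interaction. Genes outside both ranged from 10 (without mixed tumour 2) to 44 (without Py117 tumour 3), with 12 without mixed tumour 3 and 14, 13, 14 and 14 without Py8119 tumour 1, 2, 4 and 5. The position ranged from 86.3% to 88.3% and the correlation from 0.615 to 0.634. List counts, in the same order, ranged from 6 to 7, 19 to 21, 15 to 17, 14 to 17, 18 to 22, 17 to 19 and 13 to 17. With a replicate block the gene counts, in that order, were 5185, 8165, 7811, 411, 5447, 6001 and 2808, with 27 outside both, and the list counts 7, 20, 15, 17, 22, 17 and 15. Arrays with the same number correlated between groups with r from -0.234 to 0.257, and in Py117 against mixed tumours 4 of 5 arrays correlated best with their own number against 0 to 2 elsewhere, so pairing stays open. Receptor genes used as background had a 95th percentile of 5.31, and differences between genes below it are limited by background.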

Other observations

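The tests of other splits and those of immune gene positions and of Kcnma1 were chosen after the results were seen, whereas those of clock, glucocorticoid and immediate early genes were chosen before their genes were examined.

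Single genes with large differences between tumours and culture are given here. In Py117, the kallikrein-related peptidase gene Klk10 differed by -4.92 ± 0.16 from culture, Dynap by -6.15 ± 0.25 and Bpifb4 by -5.26 ± 0.14. The keratins Krt7 (-3.82 ± 0.18) and Krt14 (-3.39 ± 0.28) were lower, beyond the shift of all genes. In Py8119, the matrix gene Postn was higher by 5.77 ± 0.16, and Grem1 (-3.09 ± 0.13) and U90926 (-5.19 ± 0.11) were lower. Cdh1 was higher in Py8119 tumours than in culture by 1.36 ± 0.20.

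Other splits of the arrays into groups of the same sizes gave smaller counts for most comparisons. Of 100 splits each, only the real grouping reached its count for the parental tumours (8299 genes, highest other 767). The same held for mixed against Py117 (8007, 1243) and against Py8119 tumours (394, 0). Of 56 splits each, it held for Py117 (6811, 42) and Py8119 tumours against culture (8234, 0). This argues against chance as the source of any difference, at a share no lower than 1 of 100 or 1 of 56. Other splits mix arrays of unlike groups, so they do not test the size of the counts. For the cultures the 10 splits are too few (5942, highest other 0). For genes outside both parental tumours, 2 of 100 splits reached the real count of 23 and the highest other gave 1128. A count that high points to a structure of the samples, and that split had put 4 Py117 tumours and 1 mixed tumour in the place of the mixed group, whereas the remaining 98 splits gave 0.

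T cell, MHC class I and interferon response genes of the mixed tumours lay nearer to Py117 tumours than line genes did, whereas endothelial (90.1%), fibroblast (92.7%) and adipocyte genes (99.5%) did not, and macrophage genes had a median difference of 0.41 from Py117 and 0.026 from Py8119 tumours. Against compression of bright signals, MHC class I genes (-33.9 points ± 23.5, SD, n = 5) and T cell genes (-30.9 ± 19.3, SD, n = 5) lay lower than line genes of matched level, in 5 of 5 tumours. That all 5 showed it for MHC class I also argues against 1 or 2 unusual tumours, although mixed tumour 3 was the most extreme. Without mixed tumour 3, the mean difference was -23.6 points for MHC class I and -23.0 for T cell genes. For interferon genes the difference (-10.7 ± 10.8, SD, n = 5; 5 of 5 lower, and -6.35 without mixed tumour 3) leaves compression open. The first form of this test, with no count of tumours, would have favoured compression for interferon genes, and the count was added after that value was seen; no biological explanation was tested.

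The Kcnma1 probe set had the Py117 level in mixed tumours (position -4.06% ± 3.97, SD, n = 5), and the other Kcnma1 probe set, with a mean log2 signal of 4.18, was under background and cannot check it. A larger share of Py117 cells is argued against, since 0.823% of the 243 line genes higher in Py117 (2 genes, Kcnma1 itself and Mir5103) lay within 0.5 log2 of Py117 tumours. These 243 genes also gave the position of 86.9%, so the count is not separate evidence from that position. Compression of bright signals may contribute and stays open: 8 other genes of log2 12 or more lay at 81.2% ± 11.1 and 1023 dimmer ones at 86.9% ± 3.51 (difference -5.65 ± 9.15, SD, n = 5), too few genes to decide. A first form used the 4 line genes of log2 12 or more, Kcnma1 included (70.4% ± 4.82, SD, n = 5), which went with compression, and was replaced because it held the gene in question. No biological explanation was tested.

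Per1, Tsc22d3 and Depp1 were lower in mixed tumours than in both parental groups, and of these Per1 kept both calls without any single tumour. Against Py8119 tumours, adjusted p of Depp1 was 0.0815 and 0.0561 without mixed tumour 2 and 4 and 0.0768 and 0.0666 without Py8119 tumour 1 and 3, and that of Tsc22d3 was 0.0599 to 0.152 without mixed tumour 1, 2, 3 or 4 or Py8119 tumour 1, 3, 4 or 5. The exact permutation tests in this paragraph compared the mean of each list per array, whereas the medians given are of gene differences. A different hour of harvest may contribute and stays open. The 7 evening clock genes had medians of 0.20 against Py117 (3 called higher, and Bhlhe41 lower at -2.16) and -0.08 against Py8119 tumours (exact permutation test of list means, two-sided, p = 0.643 and 0.960). Under the rule set in advance, a median above -0.1 against 1 parental group counts against the hour of harvest. Both medians lay above that bound. The rule was set aside once the values were known. Against Py117 tumours the bound was unsuitable, since 4 of the genes differed between the parental tumours. Against Py8119 it was passed by less than the spread of the genes (SD 0.23). The left-out Nr1d1 differed by 0.58 and -0.66 (adjusted p = 0.00429 and 0.0238, the latter 0.0541 to 0.0727 without mixed tumour 3 or Py8119 tumour 1, 2, 3 or 4). The 5 morning genes had medians of -0.059 and -0.051 (exact permutation test of list means, p = 0.0159 and 0.619). Npas2, at -1.01 against Py117 tumours, weighs on that mean. Lower glucocorticoid exposure may contribute and stays open: the median of 9 induced genes was -0.34 and -0.20 (exact permutation p = 0.00794 and 0.0397), short of the -0.3 set in advance against Py8119. Immediate early genes had medians of -0.12 and 0.073 (exact permutation p = 0.111 and 0.825). Of them, 3 were called lower and 1 higher than in Py117 tumours. Under the rule set in advance, a median within 0.1 of 0 counts against handling, and the median against Py8119 tumours was. That rule was also set aside once the values were known, because genes of this list moved both ways. Handling therefore stays open too.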
